A study of Mus musculus with 2 samples.

How the data were processed

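The series holds 2 libraries of one pooled droplet experiment: mRNA of sorted conventional dendritic cells, and the hashtag antibody oligonucleotides on the same cells. Per the labels' protocols, lymph node cells were enriched by negative selection and thymus cells by CD11c-positive selection. Live lineage-negative MHC class II-positive cells were then sorted, 12500 for each preparation, and pooled after staining with hashtag antibodies against CD45 and MHC class I. The deposited values are raw UMI counts per gene or hashtag and cell barcode, written by Cell Ranger 6.0.1 per the file headers, in 1 matrix of 32285 gene rows and 4 hashtag rows. The genome build was mm10 and Seurat 4.1.1 was listed without a role, per the submitters' processing notes. The filter that chose the deposited barcodes is not given in the sources used here; the lowest held 500 UMIs. Gene names were taken from the feature table of the matrix, and the position of Etv3 from an annotation of GRCm38, the assembly also called mm10.

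Barcodes with at least 1000 mRNA UMIs, at least 500 genes and at most 10% mitochondrial UMIs were kept. Of 17998 barcodes 1378 failed, 1164 on UMIs, 1055 on genes and 852 on mitochondrial share, some on more than 1 criterion. Hashtags were called with HTODemux (Seurat 5.3.0 in R 4.3.3) after centred log-ratio scaling, with a positive quantile of 0.99. The cutoffs were 23, 432, 33 and 248 counts for hashtags 1 to 4. This gave 14288 singlets, 2162 doublets (13.0% of barcodes kept) and 170 barcodes with no hashtag; doublets and negatives were left out. From the pool sizes, 25.2% of doublets join cells of the same pool and escape this step, an expected 729 barcodes or 5.11% of the singlets. Scrublet, run within each pool, marked 18 cells (0.126%), too few to count as a working doublet call, so doublets within a pool remain in the data.

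Counts of singlets were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 with seed 0 gave 23 clusters (scanpy 1.11.5, igraph 0.11.9, Python 3.11.15). The cell type markers were fixed before the data were examined; the scoring rule was set afterwards. A cluster took the type with most markers at least 2-fold above other cells (with 20 CPM added), and needed at least 3. It stayed unnamed if its top 10 genes by fold held more markers of another type, or if it had fewer than 6 markers and none in the top 10. The classes were CCR7+ mature DC-like (5827 cells, clusters 4, 5, 11, 12, 15 and 16), cDC1-like (3172 cells, clusters 6, 13 and 14), cDC2-like (1164 cells, cluster 2), cycling (1468 cells, clusters 3, 9 and 18), monocyte or macrophage-like (865 cells, clusters 10 and 17), T cell or thymocyte-like (601 cells, clusters 8, 20 and 22), B cell-like (66 cells, cluster 0) and unnamed (1125 cells, clusters 1, 7, 19 and 21). Class names were rebuilt here and can differ from the study's own. B cell-like cells were led by plasma cell genes such as Jchain and Mzb1, and cluster 8 of the T cell-like class also by the mast cell genes Mcpt4 and Cpa3.

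UMIs were summed per class and pool and given as CPM of that sum. Intervals are exact Poisson (levels), exact conditional binomial (ratios) and exact Clopper-Pearson binomial (shares), at 95%, and cover counting error only. Cells of a class vary more than counting error, and each pool is a single preparation, so these intervals say nothing about spread between mice. A count of 0 was taken to allow 3 counts. The mature-like class held 11678082, 9600809, 1676087 and 825776 UMIs in pools 1 to 4. A gene was called higher or lower in a class when its ratio was at least 1.5-fold and its interval lay apart from 1 in each of 4 pools; the calls are descriptions, not tests. Cell type markers were left out of these counts because they define the classes. List medians were set among 10000 random lists drawn from 20 expression bins. Simulated pools with counting error alone were shallower than the real pools, though deeper than some class sums. There the ratio interval covered the true value for 96.1% of 6499 genes, which follows from that setup. Of 200 genes changed 2-fold, 88.5% had an interval apart from 1 with the right sign. These values say nothing about variation between cells.

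The genes named are Etv3, members of 15 gene lists fixed before the data were examined with at least 100 UMIs over the pools compared, and per class the 10 genes with the largest ratio of highest to lowest pool among those with at least 200 UMIs. Etv3l, Marchf1 and Mx1 of the lists were not among the gene names. Planned contrasts between genotypes within lymph node, between genotypes within thymus, and between tissues were not made, because the sources used here tie no hashtag to a tissue or genotype. Settings also tried, chosen before the data were examined, were a margin rule for hashtags (top hashtag with at least 70% of hashtag counts and at least 20 counts), a stricter cell filter (2000 UMIs, 1000 genes, 5% mitochondrial) and none, removal of Scrublet calls, Leiden resolutions 0.5 and 2.0, thinning to 2000 UMIs per cell, and equal weight for each cell. Clustering without Etv3 and the list genes that are not markers, and keeping only singlets of both hashtag rules, were added after the data were seen.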

Results

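The study asked what the ETS-family transcription factor Etv3 does in conventional dendritic cells, the antigen-presenting cells that carry antigen to T cells. Single-cell mRNA counts and hashtag antibody counts were read from one droplet experiment that pooled sorted cells of skin-draining lymph node and thymus from control and Etv3-deficient mice. The preparations had been marked with 4 hashtag antibodies before pooling, and 12500 cells of each were sorted. The cells marked by hashtags 1, 2, 3 and 4 are called pools 1, 2, 3 and 4 here. The labels and files used here did not say which hashtag marked which tissue or genotype, so no pool was given a condition, and the contrasts between genotypes and between tissues were not made. Each pool was 1 preparation with no replicate. Values are therefore given per pool with 95% counting intervals, no p-value was computed, and comparisons were made between cell classes within each pool.

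Of 17998 deposited barcodes, 16620 passed the cell filter and 14288 carried a single hashtag. Pools 1 to 4 held 3929, 3406, 3859 and 3094 cells with 17048735, 14819627, 33521137 and 25740460 mRNA UMIs. The median cell held 3888 UMIs in pool 1, 3886 in pool 2, 8402 in pool 3 and 8152.5 in pool 4, a depth gap that bears on shares of cells with a UMI and less on the level of a gene as a part of all UMIs, given here as CPM.

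CCR7+ mature dendritic cell-like cells, named by the migration genes Ccr7 and Fscn1 and other markers of activated dendritic cells, made up most of pools 1 and 2 and a small part of pools 3 and 4. They were 75.7% of cells in pool 1 (95% interval 74.4 to 77.1, exact binomial), 69.7% in pool 2 (68.1 to 71.2), 8.21% in pool 3 (7.37 to 9.13) and 5.17% in pool 4 (4.42 to 6.01). cDC1-like cells, the subset known for cross-presentation, were 5.29%, 7.84%, 35.8% and 42.5% of pools 1 to 4. cDC2-like cells were 4.33%, 3.49%, 11.2% and 14.3%, and cycling cells 2.04%, 0.851%, 21.9% and 16.6%. Monocyte or macrophage-like cells were 3.49%, 2.38%, 8.76% and 9.99% of the pools, cells of the T cell or thymocyte-like class, whose largest cluster was also led by mast cell and innate lymphoid genes, 4.15%, 8.66%, 1.40% and 2.88%, and B cell-like cells, led by immunoglobulin genes, 0.127%, 0.176%, 0.829% and 0.743%. Unnamed clusters held the remaining 4.84%, 6.90%, 11.9% and 7.79%. The sort took lineage-negative MHC class II-positive cells in equal numbers, and the labels describe a different enrichment for each tissue, so these shares need not be those of the tissues. Cluster 7, led by Il12b and Cxcl9 and kept out of the mature class by a naming threshold set after the data were seen, held 0.255%, 0.528%, 1.94% and 2.23% of pools 1 to 4. Unnamed cluster 1 held 1.58%, 2.32%, 9.10% and 4.62%. It raised 7 plasmacytoid dendritic cell and 6 cDC2 markers, and its top 10 genes included the cDC2 markers Mgl2, Cd209a and Clec10a. The order of pools 3 and 4 in cDC2-like share depends on leaving it out, and the cDC2-like contrasts leave it out too.

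**Figure D1:**
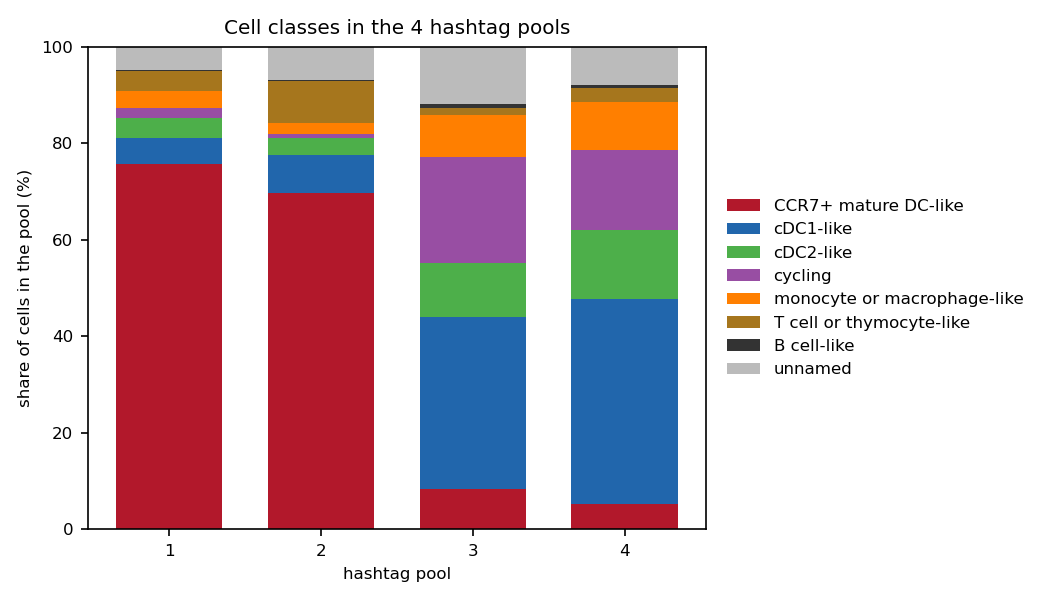
Share of cells in each class (vertical axis, percent of the cells of a pool) for the 4 hashtag pools (horizontal axis), with classes stacked to 100 percent. CCR7+ mature DC-like cells fill 75.7% of pool 1 and 69.7% of pool 2, and cDC1-like cells 35.8% of pool 3 and 42.5% of pool 4.

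Etv3 (ENSMUSG00000003382; chromosome 3, 87525577 to 87540158 of mm10), the targeted gene, was read in all 4 pools and was highest in the mature-like class. Mature-like cells held 893 Etv3 CPM in pool 1 (95% Poisson interval 876 to 911), 918 in pool 2 (898 to 937), 638 in pool 3 (600.1 to 677) and 759 in pool 4 (701 to 821). cDC1-like cells held 232, 200.2, 94.3 and 99.7 CPM, and cDC2-like cells 301, 378, 223 and 228 CPM. The ratio of mature-like over cDC1-like cells was 3.85 in pool 1 (interval 3.46 to 4.30), 4.58 in pool 2 (4.13 to 5.11), 6.76 in pool 3 (6.22 to 7.35) and 7.61 in pool 4 (6.90 to 8.40). Over cDC2-like cells it was 2.96 (2.60 to 3.40), 2.43 (2.10 to 2.83), 2.87 (2.59 to 3.17) and 3.33 (2.98 to 3.72). Cycling cells held 143, 71.8, 78.9 and 84.7 CPM and monocyte or macrophage-like cells 391, 200.6, 164 and 154 CPM. At least 1 Etv3 UMI was seen in 87.4%, 90.3%, 89.6% and 90.6% of mature-like cells of pools 1 to 4. With every cell thinned to 2000 UMIs, which left out 391, 342, 127 and 118 cells, these shares were 75.0%, 77.6%, 65.3% and 69.1%, beside 28.7%, 30.1%, 15.5% and 16.3% of cDC1-like cells. The sources used here did not give the deleted part of Etv3 or the transcript end that was counted, so these counts do not check any pool's genotype.

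**Figure D2:**
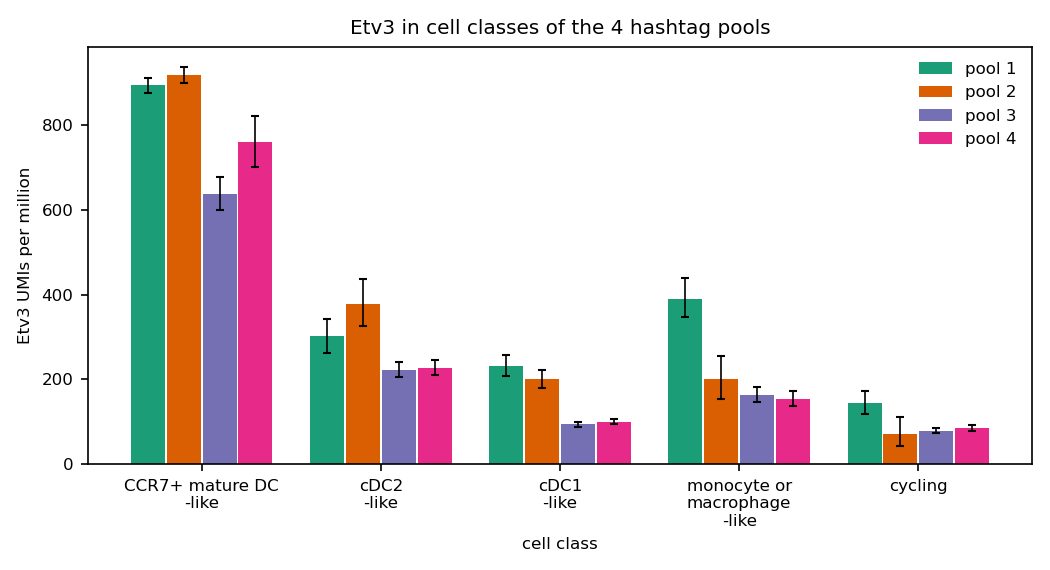
Etv3 CPM, the Etv3 UMIs over all mRNA UMIs of a class (vertical axis), in 5 cell classes (horizontal axis) of the 4 hashtag pools (bar colours), with 95% Poisson intervals as error bars. Mature DC-like cells hold 638 to 918 CPM and cDC1-like cells 94.3 to 232 CPM.

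Most NF-kB genes and some costimulation, cytokine and MHC class I genes held a larger share of UMIs in mature-like than cDC1-like cells. Several MHC class II loading and ribosome biogenesis genes held a smaller share. Both classes were compared within the same pool. The median mature-like cell held 3729.5, 3776, 5017 and 5144.5 UMIs in pools 1 to 4, beside 7445.5, 7147, 9114 and 8824 in cDC1-like cells. A higher share thus need not mean more UMIs per cell. Of the 159 genes of the fixed lists that are not cell type markers and had enough counts, 58 were higher and 25 lower in all 4 pools, by at least 1.5-fold and with a counting interval apart from 1, and 76 were called neither. Of these, 43 higher and 14 lower genes kept the call under all of 9 alternatives. In the NF-kB list 11 of 12 genes were higher, 10 of them under all 9 alternatives, and the list's median ratio lay at percentiles 99.95, 100, 100 and 100 of 10000 random lists matched on expression in pools 1 to 4. Birc2, an inhibitor of apoptosis that restrains alternative NF-kB signalling, was 16.9, 15.3, 19.7 and 20.9 times the cDC1-like level in pools 1 to 4 (pool 4 interval 18.1 to 24.0), and Nfkb2, the precursor of p52, 2.58, 3.22, 4.14 and 5.76 times. Tnfaip3, a deubiquitinase that dampens NF-kB signalling, was 4.97, 5.72, 3.38 and 4.72 times as high. Of 9 costimulation genes 5 were higher and 0 lower, among them Tnfsf9, the ligand of 4-1BB, at 4.45, 6.31, 10.9 and 9.84 times, Icosl at 3.77, 2.98, 6.33 and 4.81 times, and Icam1 at 4.51, 5.38, 3.95 and 3.70 times. Cd80 and Cd86 were not called, at 0.819, 2.06, 3.37 and 7.24 times and 0.341, 1.06, 0.527 and 1.60 times.

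Of 10 cytokine genes, 6 were higher in mature-like than cDC1-like cells and 1 was lower, but only 2 of the 6, and not the lower 1, kept the call under all 9 alternatives. Il15ra, which presents interleukin 15 to neighbouring cells, was 17.6, 10.8, 20.9 and 12.0 times as high in pools 1 to 4 and Il15 itself 19.5, 10.4, 7.88 and 3.22 times. Il12b, a subunit of interleukins 12 and 23, was 1.60, 2.64, 29.6 and 30.3 times as high, but not higher in every pool at a clustering resolution of 2.0. Of 10 MHC class I genes 5 were higher, 4 of them under all 9 alternatives, with B2m at 3.92, 3.54, 3.19 and 3.09 times and H2-K1 at 3.54, 2.59, 2.85 and 2.52 times. Of 11 survival and death genes 5 were higher, including the death receptor Fas at 20.8, 22.5, 30.1 and 14.9 times and the BCL2 relative Bcl2a1b at 4.56, 5.49, 7.87 and 7.75 times. The Fas ratios of pools 1 and 2 rest on 9 and 6 cDC1-like UMIs (intervals 10.9 to 45.5 and 10.3 to 61.5). In the tolerance-associated list, 7 of 14 genes were higher, 5 of them under all 9 alternatives, and 3 lower, 0 of them under all 9; Socs1, a feedback inhibitor of cytokine signalling, was 5.55, 9.34, 6.36 and 3.34 times as high. Of 12 cholesterol genes 4 were higher, 3 of them under all 9 alternatives, and 0 lower. Idi1, an enzyme of isoprenoid and sterol synthesis, was 21.2, 9.67, 26.1 and 7.08 times and the sterol exporter Abcg1 7.20, 2.97, 5.99 and 2.21 times as high. Of 9 phagocytosis and lysosome genes 4 were higher and 2 lower, with Lamp1 16.5, 7.81, 24.6 and 11.8 times and Lgmn 10.1, 7.87, 11.7 and 9.79 times as high.

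The MHC class II list had 0 of 12 genes higher and 4 lower in mature-like cells, 3 of them under all 9 alternatives; H2-Ob lost the call under the stricter cell filter. Its median ratio lay at percentile 0 of the random lists in pools 1, 2 and 3 and at 12.1 in pool 4. H2-DMb1, a chain of the class II peptide-loading molecule H2-DM, stood at 0.0596, 0.0899, 0.0943 and 0.159 of the cDC1-like level in pools 1 to 4. H2-DMa stood at 0.0789, 0.171, 0.198 and 0.547. Among the genes called neither, H2-Aa, H2-Ab1, H2-Eb1, Cd74, H2-Oa and Ciita were lower in 3 pools. H2-DMb2 went both ways, at 0.301, 0.434, 1.55 and 3.69, and Ctss stood above the cDC1-like level, at 1.91, 2.65, 1.47 and 2.54. In the MYC and ribosome biogenesis list 0 of 11 genes were higher and 6 lower, of which Nop56 and Ncl lost the call under 6 and 3 of the 9 alternatives. Fbl, the small nucleolar methyltransferase fibrillarin, stood at 0.223, 0.226, 0.201 and 0.224 and Ldha at 0.138, 0.282, 0.149 and 0.255. The scavenger receptor gene Cd36 stood at 0.0369, 0.0319, 0.0418 and 0.0431. Other lists were mixed: chemokines had 2 of 9 genes higher and 3 lower (2 and 2 under all 9 alternatives, without Cxcl9), interferon-stimulated genes 3 of 14 higher and 3 lower (1 and 0 under all 9 alternatives), migration genes 2 of 6 higher and 2 lower (2 and 1), and immediate-early stress genes 2 of 13 higher and 1 lower (1 and 1). Among the 12 ETS-family genes read, Etv3, Elk3, Ets1, Ets2 and Spib were higher and Fli1 was lower. Ets2 lost the call under 6 of the 9 alternatives, and Ets1 and Spib lost it after thinning. With cells thinned to 2000 UMIs, 47 of the 58 higher and 19 of the 25 lower genes still met the criteria, and 0 changed direction.

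Against cDC2-like cells most MHC class I genes and 6 of 11 survival and death genes were higher in mature-like cells, and several chemokine genes were lower. Of 158 list genes 31 were higher, 35 lower and 92 were called neither in all 4 pools, and 23 of the higher and 21 of the lower kept the call under all 9 alternatives. MHC class I genes were higher for 7 of 10, with B2m at 2.95, 2.61, 2.57 and 2.13 times the cDC2-like level in pools 1 to 4 and Psmb9, a subunit of the immunoproteasome, at 3.17, 3.27, 1.83 and 1.59 times. Tap1, Tap2 and H2-D1 of the 7 lost the call under 4, 5 and 1 of the 9 alternatives. Of the survival and death genes 5 of the 6 kept the call under all 9 alternatives, and 1 gene, Bcl2, was lower, though not after thinning; the executioner caspase gene Casp3 was 9.74, 4.47, 6.51 and 4.59 times as high and Bcl2a1d 1.87, 2.29, 1.82 and 2.20 times. In the NF-kB list 5 of 12 genes were higher, 4 of them under all 9 alternatives, with Birc2 at 10.2, 5.95, 7.47 and 8.9998 times. Of 9 cytokine genes 4 were higher and 2 lower (3 and 2 under all 9 alternatives). Il12b was 64.2, 55.4, 148 and 68.8 times as high. In pools 1 and 2 its cDC2-like level lay near the floor of 3 UMIs, which is 3.98 and 6.12 CPM, so those ratios are imprecise. The inflammasome-processed cytokine gene Il1b stood at 0.146, 0.305, 0.146 and 0.184. Of 9 costimulation genes 2 were higher and 1 lower; Icam1 was 3.78, 1.92, 3.01 and 2.59 times as high and Cd48 stood at 0.308, 0.575, 0.373 and 0.596.

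Chemokines had 1 of 9 genes higher and 5 lower against cDC2-like cells. Cxcl16 was 6.27, 4.22, 2.87 and 2.19 times as high, whereas Ccl4, an attractant of CCR5-bearing cells, stood at 0.138, 0.0697, 0.120 and 0.0673 and Ccl3 at 0.188, 0.0386, 0.0823 and 0.158. Of 10 phagocytosis and lysosome genes 0 were higher and 4 lower, 2 of them under all 9 alternatives, with the macrophage glycoprotein gene Cd68 at 0.0596, 0.216, 0.108 and 0.248. MHC class II genes were lower for 5 of 12 and higher for 0, with H2-DMa at 0.0738, 0.194, 0.178 and 0.502, but H2-Ab1 lost the call under 5 of the 9 alternatives and Ciita under the stricter filter. MYC and ribosome biogenesis genes were lower for 5 of 10, 3 of them under all 9 alternatives, with Fbl at 0.239, 0.235, 0.222 and 0.270, and immediate-early genes for 3 of 13, with Nr4a1 at 0.246, 0.256, 0.270 and 0.488. Tolerance-associated genes went both ways, 3 of 14 higher and 6 lower (2 and 3 under all 9 alternatives). Of the remaining lists, 1 of 12 cholesterol genes was higher and 0 lower. Interferon-stimulated genes were higher for 1 of 14 and lower for 2, and migration genes higher for 1 of 6 and lower for 2. Under all 9 alternatives 0 of these lower genes kept the call. The interferon list's median ratio lay at percentiles 0.33, 99.3, 0.02 and 0.05 of the random lists, low in pools 1, 3 and 4 and high in pool 2. Of 12 ETS-family genes Etv3 and Elk3 were higher and Fli1 lower, but Elk3 lost the call under all 9 alternatives and Fli1 after thinning. With cells thinned to 2000 UMIs, 24 of the 31 higher and 26 of the 35 lower genes still met the criteria, and 0 changed direction.

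Within the mature-like class, the 4 pools differed most, by list sums, in MHC class II, chemokine, interferon and cholesterol genes. Different clusters held the class in each pool: clusters 5, 15 and 12 held 1453, 1008 and 474 of the 2976 cells of pool 1, clusters 16, 11 and 4 held 1106, 691 and 502 of the 2374 of pool 2, clusters 15 and 5 held 161 and 140 of the 317 of pool 3, and clusters 4 and 11 held 80 and 51 of the 160 of pool 4. The 12 MHC class II genes summed to 11057 CPM in pool 1, 13133 in pool 2, 31590 in pool 3 and 49516 in pool 4 (interval 49037 to 49998), and 11 of the 12 were highest in pool 4. The class II invariant chain gene Cd74 held 5062, 5263, 14114 and 17949 CPM and the class II transactivator gene Ciita 13.1, 10.4, 40.6 and 89.6 CPM. H2-Ab1 held 993, 1518, 4101 and 9266 CPM, where the pool 3 value was 7543 under the stricter cell filter; that of Ciita was then 63.8. In cDC1-like cells the class II sum ranged from 57705 to 59284 CPM. The cDC1 marker Clec9a, chosen after its values were seen, also stood higher in the mature-like class of pools 3 and 4, at 0.0337, 0.0303, 0.117 and 0.0792 of the cDC1-like level from 68, 58, 31 and 12 UMIs. Tlr3, another cDC1 marker, stood at 0.0368, 0.0126, 0.0466 and 0.0137 from 21, 9, 5 and 1 UMIs, lower in pool 4 than in pool 1. Whether cDC1 RNA in the class adds to its class II difference was not tested.

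The costimulation list summed to 1111, 1314, 1276 and 1595 CPM, but single members moved apart further. The ligand genes Cd80 and Cd86, which bind CD28 and CTLA4 on T cells, held 29.6, 93.0, 71.6 and 163 CPM and 76.9, 210.2, 133 and 397 CPM in mature-like cells of pools 1 to 4. Tnfsf4, the OX40 ligand gene, held 11.1, 83.0, 13.1 and 67.8 CPM (pool 4 interval 51.2 to 88.1), moving to 8.59 CPM in pool 3 when clustered without the list genes and to 40.05 CPM in pool 4 under the stricter filter. Cd40, the receptor of CD40 ligand, differed less, at 289, 244, 359 and 268 CPM. The cholesterol list summed to 1139, 549, 974 and 591 CPM. Idi1 held 227, 64.0, 243 and 56.9 CPM, Hmgcs1, the synthase before HMG-CoA reductase, 77.5, 14.8, 45.3 and 15.7 CPM, and Abcg1 304, 133, 304 and 102 CPM, while the lipoprotein gene Apoe held 67.9, 89.0, 121 and 191 CPM. Interferon-stimulated genes summed to 649.9, 572, 1630 and 1433 CPM, with the ubiquitin-like modifier gene Isg15 at 68.6, 43.5, 386 and 293 CPM and the transcription factor gene Stat1 at 96.6, 157, 184 and 256 CPM. Without a cell filter Isg15 held 458 CPM in pool 4, and after thinning Hmgcs1 held 10.1 CPM there.

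Chemokine genes summed to 24579, 19978, 13224 and 7581 CPM in mature-like cells, most of it Ccl5 at 21876, 16936, 9648 and 4906 CPM. Ccl17, an attractant of CCR4-bearing T cells, held 218, 73.4, 515 and 180.4 CPM and the interferon-induced Cxcl10 56.8, 249.9, 45.9 and 176 CPM. The pool 4 values of Ccl5 and Ccl17 moved to 3122 CPM under the stricter cell filter and to 284 CPM with no filter, respectively. Of the tolerance-associated genes, Socs2 held 474, 152, 539 and 228 CPM, Aldh1a2, which makes retinoic acid, 28.7, 3.12, 19.7 and 3.63 CPM, the last from 3 UMIs, and Cd274, which encodes PD-L1, 177, 260.4, 217 and 372 CPM. Under the stricter filter Socs2 held 150.4 CPM in pool 4, and Aldh1a2 held 9.90 CPM in pool 3 after thinning and 2.10 in pool 4 when clustered without the list genes. Il12b held 256, 565, 827 and 1075 CPM and Il1b 277, 715, 153 and 249 CPM, or 99.9 in pool 3 at a clustering resolution of 2.0. MHC class I genes summed to 19132, 16052, 20406 and 18448 CPM, NF-kB genes to 8453, 9223, 6201 and 8137 CPM, and migration genes to 18230, 22169, 18562 and 20232 CPM. The lysosomal gene Lamp1 held 731, 190, 814 and 304 CPM, and the calcium-binding S100a6 637, 1743, 595 and 1332 CPM.

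**Figure D3:**
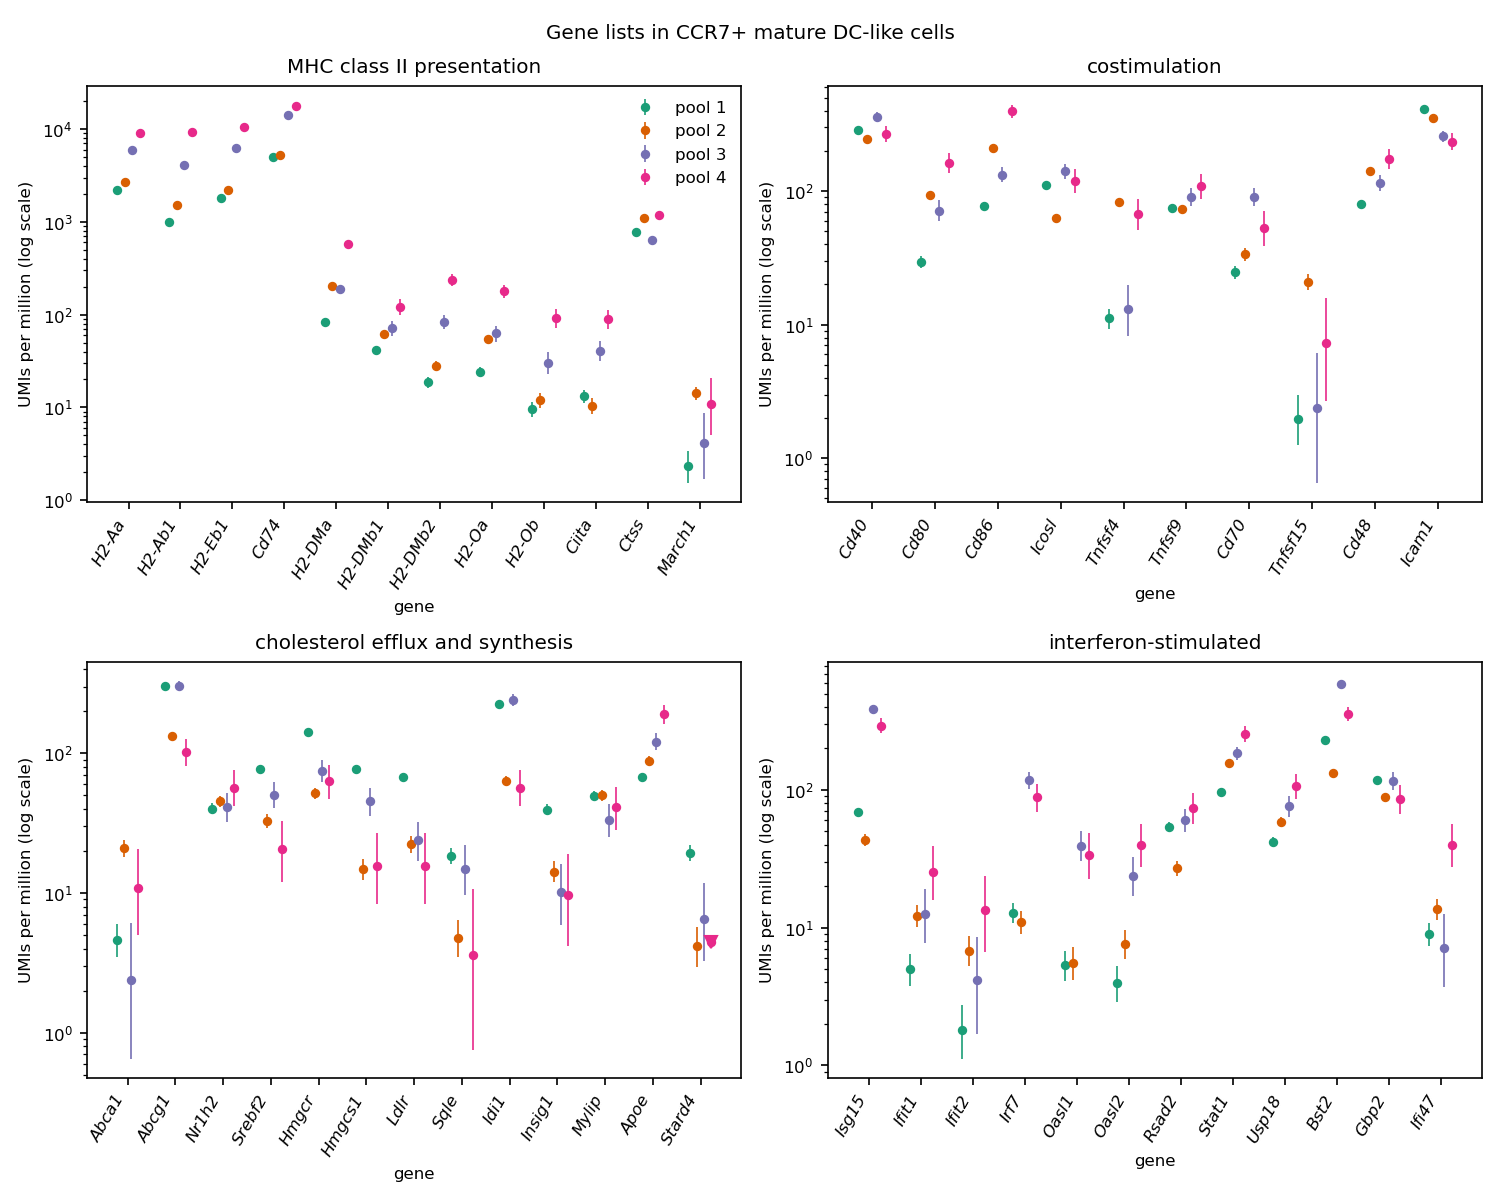
CPM (vertical axes, log scale) of the genes (horizontal axes) of 4 lists in CCR7+ mature DC-like cells, with a point per hashtag pool and 95% Poisson intervals as bars. A downward triangle marks the upper bound of a gene with 0 UMIs, Stard4 in pool 4; H2-Ab1 runs from 993 to 9266 CPM and Idi1 from 56.9 to 243 CPM.

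Over all genes with at least 200 UMIs in the mature-like class, the 10 with the largest ratio of highest to lowest pool included the Langerhans cell lectin gene Cd207 at 23.5, 244, 7.76 and 8.48 CPM in pools 1 to 4. Its pool 3 and pool 4 values came from 13 and 7 UMIs and were 32.9 and 39.3 CPM under the stricter filter. Klrb1b, a lectin-like receptor gene, held 2.65, 25.9, 1.19 and 42.4 CPM and Tespa1, known from thymocyte signalling, 2.31, 62.5, 5.97 and 114 CPM. The long noncoding RNAs 1110002J07Rik and Gm34084 held 1.03, 28.2, 0.597 and 73.9 CPM and 5.14, 70.2, 48.9 and 363 CPM. Plat, which encodes tissue plasminogen activator, held 40.5, 13.2, 5.37 and 1.21 CPM and Lsmem1 9.50, 19.3, 0.597 and 6.05 CPM. Sod3, the extracellular superoxide dismutase gene, held 17.8, 0.417 and 5.37 CPM in pools 1 to 3, Pcdh7 4.97, 20.2 and 0.597 CPM and Tcim 32.0, 38.1 and 1.19 CPM. Those 3 genes had 0 of 825776 UMIs in pool 4, which allows up to 3.63 CPM. The pool 3 values of all but Gm34084 rest on 1 to 13 UMIs and moved by over 1.5 times under at least 1 alternative, as did the pool 4 values of Plat and Lsmem1 and the pool 2 value of Sod3.

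In cDC1-like cells, 3 of the 10 genes came from the interferon list: Isg15 at 47.6, 13.2, 211 and 246 CPM in pools 1 to 4, Usp18 at 10.1, 3.86, 57.7 and 65.6 CPM and Oasl1 at 2.01, 1.65, 23.1 and 27.7 CPM. Whether that is more than chance was not tested. Oas1a held 3.35, 1.103, 23.9 and 19.7 CPM and the Schlafen gene Slfn1 2.01, 0.551, 41.9 and 38.8 CPM. The whole interferon list summed to 534, 468, 1365 and 1505 CPM. Mt3, a metallothionein gene, held 0.670, 0, 67.0 and 28.3 CPM, its pool 2 value of 0 of 1813592 UMIs allowing up to 1.65 CPM, and Epcam, an adhesion molecule gene, 6.70, 2.21, 47.2 and 28.3 CPM. Tcea3 held 0.670, 1.65, 15.7 and 11.2 CPM, Gm15472 1.34, 0.551, 10.5 and 12.6 CPM and the matrix metalloproteinase gene Mmp14 0.670, 1.103, 11.4 and 8.13 CPM. Cluster 6 held 150 and 200 of the 208 and 267 cDC1-like cells of pools 1 and 2. Cluster 13 held 820 and 708 of the 1382 and 1315 of pools 3 and 4, where cluster 14, itself led by Mt3 and Irf7, held a further 442 and 397. All values of these genes in pools 1 and 2 rest on 0 to 71 UMIs, and most of the genes moved there by over 1.5 times under at least 1 alternative, Isg15 in pool 2 to 32.9 CPM without a cell filter.

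In cDC2-like cells, a single cluster in all pools, Ly6a held 41.1, 10.2, 376 and 605 CPM, Slfn1 3.98, 2.04, 91.7 and 108 CPM, Oasl2 11.9, 2.04, 75.6 and 91.2 CPM and Ms4a6d 26.5, 6.12, 231 and 247 CPM in pools 1 to 4. The chemokine gene Ccl17 held 14.6, 18.4, 538 and 700.1 CPM, the integrin gene Itgae 1.33, 0, 61.6 and 66.0 CPM, and Plet1, a surface protein gene, 0, 6.12, 114 and 136 CPM. Aqp3 held 1.33, 4.08, 55.7 and 42.2 CPM, the cytokine signalling inhibitor gene Cish 2.65, 2.04, 48.0 and 74.9 CPM, and Kctd14 18.6, 2.04, 62.7 and 48.3 CPM. These classes were small in pools 1 and 2, with 170 and 119 cells. The 10 genes' values there rest on 0 to 31 UMIs each, and all 10 genes moved in pool 1 or 2 by over 1.5 times under at least 1 alternative, by up to 9.45 times for Aqp3 in pool 1. Without a cell filter the pool 3 values of Ly6a, Slfn1, Ccl17, Itgae, Oasl2, Cish and Plet1 fell by more than 1.5 times, Ccl17 to 271 CPM, as did Slfn1 in pool 4, to 70.4 CPM.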

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

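Some barcodes that the main comparisons left out carried hashtag counts. Of the 170 barcodes without a called hashtag, 145 had hashtag 2 as their highest, with a median hashtag 2 count of 313.5 over all 170 barcodes, below the cutoff of 432 counts for that hashtag. The median own-hashtag count of called cells was 915, 1246, 1278 and 1194 in pools 1 to 4. The margin rule called 824 of the HTODemux doublets and 150 of the barcodes without a hashtag singlets, and they entered the alternative with that rule. The files used here hold no unstained cells that would set a background. Mature-like cells called for pools 1, 3 and 4 held a median of 11, 11 and 10 counts of hashtag 2, far below 313.5. The typical uncalled barcode thus held more hashtag 2 than cells of the other pools. Its source was not tested, and the other hashtags were not compared in this way.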

How the results depend on the processing

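Settings moved the share of mature-like cells and ended some calls of the class contrasts. The mature-like share was 69.7% and 64.2% in pools 1 and 2 without a cell filter. In pool 3 it was 10.6% with the stricter filter, 10.1% with none, 10.7% at resolution 0.5, 10.96% clustered without the list genes and 10.2% for singlets by both hashtag rules. In pool 4 it was 7.68% with the stricter filter, 7.14% at resolution 0.5, 4.33% at 2.0, 7.60% without the list genes and 7.38% by both rules. The ratio of Etv3 in mature-like over cDC1-like cells moved to 3.37 in pool 1 at resolution 2.0, 4.11 in pool 2 with equal weight per cell, 7.38 in pool 3 after thinning, and 6.85 and 6.74 in pool 4 without a filter and with both rules. The cause was not tested. Over 10 alternatives, the added 2 included, 5156 of 6588 recomputed values stayed within their interval or 1.5 times the main count. Another 1432 moved and 0 were marked as reversed. Most of these values are levels, shares or counts of a single pool, which have no direction that could reverse. The order of pools was not part of that count and did change for some genes. Irf7 in mature-like cells held 118 and 88.4 CPM in pools 3 and 4, but 214 and 225 CPM at resolution 0.5. Of the genes higher than in cDC1-like cells, 47 to 57 of 58 kept the call, depending on which of 9 alternatives was used, and 17 to 24 of the 25 lower; against cDC2-like cells 24 to 30 of 31 and 26 to 35 of 35 did. Values on few UMIs moved more often: 228 of 830 values resting on under 20 UMIs moved by over 1.5 times, 67 of 990 on 20 to 99 UMIs, 64 of 4220 on 100 or more, and 0 of 360 list sums. Values with more counts moved too, such as H2-Ab1 in mature-like cells of pool 3, with 6873 UMIs, by 1.84 times, and Cxcl9 there, with 46 UMIs, by 9.41 times when clustered without the list genes. Whether depth or a change in the cells of a class moved a value was not tested. Contrasts between genotypes and tissues, and their alternatives, were not run. No paired analysis was possible because no group has replicates.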

Other observations

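Lymphoid clusters were unevenly spread over the pools despite the lineage-negative sort. Cluster 21, led by Areg, Gata3 and Il13, genes known from type 2 innate lymphoid and T cells, held 87 and 104 cells in pools 1 and 2 and 0 in pools 3 and 4, which allows shares up to 0.0777% and 0.0970%. Cluster 22, led by Cd3g and Il17a, held 60, 143, 1 and 0 cells. Cluster 20, led by the thymocyte genes Dntt and Cd8b1, held 0, 0, 17 and 21 cells. Cluster 17, led by the macrophage genes Retnla and Fn1, held 0, 2, 42 and 52 cells. Cluster 1, led by Cd209d, Cd209e, Tcf4 and the cDC2 markers Mgl2 and Cd209a, held 62, 79, 351 and 143. Clusters 7 and 19, kept out of the mature and cDC2 classes by the naming threshold, held 10, 18, 75 and 69 and 31, 34, 33 and 29 cells.

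The remaining gene lists in the mature-like class differed less between pools, by their sums, than the MHC class II, chemokine, interferon and cholesterol lists. Immediate-early genes such as Fos, Junb and Zfp36 summed to 12474, 13039, 7679 and 9813 CPM in pools 1 to 4, with Egr1 at 387, 174, 128 and 70.2 CPM. Survival and death genes summed to 3887, 4715, 4496 and 4997 CPM, tolerance-associated genes to 7921, 8001, 6018 and 7434 CPM and cytokines to 1011, 1735, 1386 and 1686 CPM. MYC and ribosome biogenesis genes summed to 1559, 1637, 1233 and 1332 CPM, phagocytosis and lysosome genes to 1525, 1083, 1603 and 1318 CPM, and ETS-family genes to 1531, 1663, 1279 and 1494 CPM.

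Of the tests below, those of hashtag spillover, depth and the share of cDC1 and cDC2 were chosen or amended after the result was seen, as were the ratios of Ccl22 and of Fscn1 in pools 2 to 4 in T cell-like barcodes; the other tests of these barcodes were fixed before. Across 6711 genes of the mature-like class, which are not independent replicates, the log2 differences between pools 2 and 1 and between pools 4 and 3 correlated with r = 0.695, those between pools 3 and 1 and pools 4 and 2 with r = 0.652, and the remaining pairing gave r = -0.0790. In pools simulated from a common profile with counting error alone, the same pairings gave -0.0174, -0.0127 and -0.00205. Such pools hold no variation between cells or clusters, so these low values follow from the setup. In cDC1-like cells the pairings gave 0.142, 0.757 and 0.708, and in cDC2-like cells 0.243, 0.791 and 0.703.

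For the difference shared by pools 2 and 1 and pools 4 and 3 in mature-like cells, the tables argue against miscalled hashtags as the whole cause. Mature-like cells of pools 3 and 4 held a median of 1459 and 1115 counts of their own hashtag, beside 1226 and 1136 in cDC1-like cells of these pools. Over the 198 and 78 mature-like cells at or above the cDC1-like median r was 0.634 (0.613 to 0.660 over resampled genes). Unequal depth is also argued against as the whole cause, since the median UMIs of mature-like cells differed little within the pairs. The ratio was 1.012 between pools 2 and 1 (0.986 to 1.041 over resampled cells) and 1.025 between pools 4 and 3 (0.904 to 1.121). With every cell thinned to 2000 UMIs r was 0.561 (0.536 to 0.585 over resampled genes), below the 0.695 over all counts. Whether the lost counts alone explain this fall was not tested. Over 4057 genes that differed by less than 1.2-fold between cDC1-like and cDC2-like cells r was 0.627 (0.598 to 0.658). This cannot decide on an unequal share of these subsets within the mature-like class. Genes alike in these 2 classes may still differ between mature cells that arose from them. The share of cDC1 and cDC2 stays open, and other mixtures of subsets and free RNA were not tested. The tissue and the genotype of the mice stay open and untested, since no hashtag is tied to a condition. Cluster 20, led by thymocyte genes, held 0, 0, 17 and 21 cells in pools 1 to 4. That split lies between the pairs and not within them, but so few cells tie no hashtag to a tissue.

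Barcodes of the T cell or thymocyte-like class carried dendritic cell RNA. The class is not T cells alone: cluster 8, with 359 of its 601 barcodes, was led by the mast cell genes Mcpt4, Cma1 and Cpa3 and by Xcl1 and Il22 beside Trbc1 and Trbc2. Fscn1 held 897, 773, 264 and 75.2 CPM in the class in pools 1 to 4, and 147 barcodes had at least 2 Fscn1 UMIs while 400 had none. Of the 147, 58.5% had a Cd3d, Cd3e or Cd3g UMI. For Fscn1, free RNA is argued against in pools 1 to 3. The Fscn1 level was 31.1 times (22.8 to 43.5) that of cDC1-like cells of the same pool in pool 1. In pools 2 and 3 it was 40.05 times (28.6 to 57.9) and 15.9 times (12.1 to 20.7). In pool 4 it was 5.33 times (3.53 to 7.83), from 32 UMIs. This cannot decide on free RNA there, which takes a larger share of shallow barcodes. The class held a median of 2638 UMIs in pool 4, beside 8824 in cDC1-like cells. The ratios of Ccl22 were 12.2, 20.997, 2.56 and 1.06 (pool 4 interval 0.478 to 2.04), so free RNA stays open for Ccl22 in pools 3 and 4. Barcodes with at least 2 Fscn1 UMIs held a median of 6115 UMIs against 2495 in those with none, 2.45 times as many (2.28 to 2.63 over resampled barcodes), and mature-like cells of pools 1 and 2 held 3729.5 and 3776. Doublets of a cell of this class and a mature dendritic cell are a candidate explanation for Fscn1, as a hypothesis. At the main settings they alone do not account for H2-Ab1 in pool 3, at 6229 CPM in the class and 4101 CPM in mature-like cells. The mature-like value was 7543 CPM under the stricter cell filter, so this comparison depends on the setting. In cDC1-like cells of pool 3 H2-Ab1 held 13174.5 CPM. Doublets with cDC1-like cells were not tested, and the source of this H2-Ab1 RNA stays open. Deeper barcodes also have more chance of a second UMI, and no biological explanation was tested.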
